A study of Mus musculus with 8 samples.

How the data were processed

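Polyadenylated RNA from the forebrain of mice aged 18 months was measured in 8 libraries, 4 of TgCRND8 transgenics (Tg) and 4 of non-transgenic littermates (NTg). Per the labels' protocols, RNA was extracted from pulverised frozen tissue, libraries were made with the TruSeq RNA kit version 2, which does not mark strand, and sequenced in pools as paired-end 75-base reads on a NextSeq 500. All libraries carry the same value, F, under batch, which could also stand for the sex, so no batch split could be made. The labels number the replicates of each genotype and name littermates, but do not say outright that each library is a separate animal. If some are not, the p-values measure only the spread between these libraries.

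The authors deposited a table of raw read counts per Ensembl gene, with no normalization, for 56748 genes in 8 libraries. Per the submitters' processing notes, STAR, DESeq2 and the build GRCm39 were used. The counting tool, the annotation release and all versions are not given in the sources used here, so genes that overlap or have near-identical copies, such as the haemoglobin genes, carry uncertain counts. No row lacked a gene identifier, and 0 columns belonged to other series. Symbols were matched by Ensembl identifier to a name table, which gave a symbol to 52073 identifiers holding 99.58% of the counts. Gene order along the chromosome was taken from GENCODE mouse release M21, which is on an older build than the counts, so it was used for neighbour order alone and no coordinates are given.

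Library totals were 57129090 to 65242741 counts. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 21588, and 39716 genes had a count in any library. Counts were scaled with TMM factors and tested with edgeR's quasi-likelihood F test without robust dispersion, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM values come from edgeR's cpm function on TMM-scaled library sizes, given as mean ± SD of 4 libraries, and the SE of a log2 fold change is its size divided by the square root of F. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

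Before the data were examined, 42 gene lists (cell types, brain regions and pathways) were fixed, with 620 distinct genes, of which 598 were tested. The 41 lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01, two-sided, on voom values), with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. For each list the members passing edgeR are counted over all genes tested and also adjusted over the list alone. The position of a library in a list is the mean log2 CPM (prior count 2) of its members relative to the mean of the NTg libraries. Single values per library were compared by exact two-sided permutation tests, whose smallest p is 0.0286 for 4 against 4.

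The rule for named genes was also fixed in advance: App and Prnp, then, among called genes whose genotypes do not overlap, up to 16 rises and 10 falls with the smallest p and the 10 largest rises, without symbols of the predicted or clone type, up to 4 called members of each list, and up to 2 of the most abundant members of a list with none. Since edgeR called 3 genes, most members named for a list fall outside this rule and were chosen after their values were seen. Some of the most abundant members are not named. Some genes once among them are not reported here and are left out of the counts made over named genes. Y-linked genes and Xist served only to check the sex of the libraries.

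Alternatives planned in advance were DESeq2, limma-voom, other scaling factors, no or a stricter filter on low counts, the replicate number as a block, 1 surrogate variable, robust dispersion, each library left out in turn, an FDR of 0.01, a minimum fold of 1.2, and the removal of clone-type genes or of members shared between lists. Library quality weights, edgeR's likelihood ratio test, and the red blood cell or choroid plexus level as a covariate were added after seeing the data. Tested on counts simulated from these libraries (21332 genes tested, 200 changed), edgeR recovered 62.7% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 3-fold, with 17 false calls. On the same counts DESeq2 recovered 68.7%, 91.0% and 100%, with 61 false calls. The simulated genes varied independently and no library was set apart, so these shares need not hold for the real libraries. A comparison of counts within each genotype gave a chi-square per degree of freedom of 10.1 or more for every pair of libraries, so no pair agreed within sampling noise.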

Results

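The forebrain transcriptome of TgCRND8 mice, a line that overexpresses the human amyloid precursor protein (APP) and develops amyloid plaques, was compared with that of non-transgenic littermates at 18 months of age. RNA from pulverised frozen forebrain was sequenced for 4 transgenic (Tg) and 4 non-transgenic (NTg) libraries. Each library held 57129090 to 65242741 counts over 56748 genes, and 21588 genes were abundant enough to be tested. All 8 libraries looked female, with Xist at 526 to 753 CPM (counts scaled to a common library size) and 0 to 2 counts in total over 4 Y-linked genes. The question the design poses is which genes and cell-type programmes differ between the genotypes in aged tissue labelled forebrain, and every fold change below is Tg over NTg.

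App, the mouse gene to which reads of the human transgene can align in part, rose from 1488 ± 98.4 to 2851 ± 213 CPM (SD, n = 4; log2 fold change 0.94, SE 0.07, edgeR adjusted p = 0.00146). Its 4 Tg libraries, at 2532, 2934, 2980 and 2958 CPM, all lay above the highest NTg library at 1623 CPM. Prnp, the prion protein gene, whose hamster counterpart is part of the vector of this line, stood at 700 ± 23.3 CPM in NTg and 704 ± 27.0 CPM in Tg (log2 fold change 0.01, SE 0.05, adjusted p = 0.992). How many of the App counts came from the human sequence is not given by gene-level counts.

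Beside App, the quasi-likelihood test of edgeR called Cxcl10 and Prmt3, which makes 3 genes at an FDR of 0.05. Cxcl10, an interferon-induced chemokine, rose from 0.485 ± 0.121 to 4.22 ± 1.14 CPM (log2 fold change 3.11, SE 0.24, adjusted p = 0.00146, n = 4), with 3.00 to 5.74 CPM in the Tg libraries. Prmt3, a protein arginine methyltransferase, fell from 24.6 ± 0.740 to 13.7 ± 0.261 CPM (log2 fold change -0.85, SE 0.05, adjusted p = 0.000242), and the 4 Tg libraries lay between 13.3 and 13.9 CPM. At an unadjusted p under 0.05, 1589 genes differed, 1011 higher and 578 lower in Tg, where 1079 are expected by chance. DESeq2, the tool in the submitters' processing notes, called 352 genes on the same counts, 287 higher and 65 lower, and all 3 edgeR calls were among them. The edgeR count was 314 without Tg replicate 1, 16 without NTg replicate 1, 9 without Tg replicate 2 and 127 with no filter on low counts.

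Microglial genes stood higher in Tg as a group. Of the 25 disease-associated microglia genes, which mark phagocytic microglia around plaques, 20 rose when adjusted over the list alone, with a median log2 fold change of 0.80. Over all genes tested edgeR called 0 of them and DESeq2 16. Trem2, a lipid receptor of microglia, went from 17.8 ± 2.87 to 52.3 ± 14.1 CPM (SD, n = 4; log2 fold change 1.56, SE 0.20; adjusted p = 0.000350 over the list alone and 0.0723 over all genes), and Cst7, a cystatin, from 2.83 ± 1.32 to 23.8 ± 9.48 CPM (log2 fold change 3.06, SE 0.41). Cd68, a phagocytic marker, went from 10.7 to 27.2 CPM and Apoe, the most abundant member, from 1410 to 1661 CPM. Genes of homeostatic microglia did not go the other way: 11 of 13 also rose when adjusted over the list alone, with a median of 0.61, among them Gpr34 (17.5 to 29.6 CPM), the fractalkine receptor Cx3cr1 (46.6 to 73.9 CPM), Csf1r (72.4 to 111 CPM) and P2ry12 (31.9 to 43.1 CPM). The excess of the disease-associated over the homeostatic list was 0.26 ± 0.15 on the log2 scale in Tg and 0 ± 0.30 in NTg (SD, n = 4; exact two-sided permutation p = 0.171). Tg replicate 1 lay nearest to the NTg libraries, at 0.37 above the NTg mean in the disease-associated list where the other Tg libraries lay at 1.01 to 1.08. Without it, edgeR called 18 of the 25 disease-associated and 7 of the 13 homeostatic genes over all genes. Camera gave adjusted p = 2.76e-25 and 3.33e-15 for these lists, but 0.148 for both with an estimated correlation between members. Named members beyond the 2 most abundant of each list, here and below, were chosen after their values were seen.

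Lists tied to phagocytosis and innate sensing moved the same way. Of 23 lysosomal genes, 18 rose when adjusted over the list alone (median log2 fold change 0.44), with the cathepsins Ctss (98.9 ± 12.1 to 188 ± 34.6 CPM) and Ctsd (243 ± 16.5 to 435 ± 99.2 CPM) and the membrane protein Laptm5 (44.9 to 93.2 CPM). Of 22 innate and Fc receptor genes, 15 rose by the same measure (median 0.73), including Ly86 (13.1 to 26.9 CPM) and the RNA sensor Tlr7 (3.92 to 8.04 CPM). Of 15 complement genes, 9 rose (median 0.69), including C1qa (59.8 to 127 CPM), C4b (138 to 333 CPM) and the C3a receptor C3ar1 (4.47 to 9.38 CPM), again when adjusted over the list alone. Of 16 genes in the list of Alzheimer risk genes of myeloid cells, 10 rose when adjusted over the list alone (median 0.59). Among them the myeloid transcription factor Spi1 went from 3.61 to 5.66 CPM and the inhibitory receptor Lilrb4a from 1.49 to 4.89 CPM. The 2 most abundant members, not among the 10, were Sorl1 (339 to 367 CPM) and Ptk2b (304 to 273 CPM), whose counts in whole tissue need not come from myeloid cells. In this list NTg replicate 1, at 0.26, lay above Tg replicate 1, at 0.20 (exact two-sided permutation p = 0.0571 between genotypes). Likewise not called were the most abundant lysosomal gene, Psap (1417 to 1441 CPM), and receptor gene, Mertk (25.97 to 25.65 CPM). Over all genes edgeR called 0 members of these 4 lists and DESeq2 called 17, 11, 6 and 7. Camera's adjusted p was 2.78e-26 for the lysosome, 9.03e-18 for the receptors, 6.15e-11 for complement and 1.70e-10 for the risk genes, against 0.148, 0.167, 0.148 and 0.200 with an estimated correlation. Tg replicate 1 was 0.18 above the NTg mean in the lysosome list, against 0.60 to 0.64 in the other Tg libraries. Without it edgeR called 16 lysosomal, 11 receptor, 8 complement and 7 risk genes over all genes.

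Interferon-response genes stood higher in Tg, with 12 of 24 rising when adjusted over the list alone (median log2 fold change 0.43) and 1, Cxcl10, over all genes. Bst2, a membrane tether of viruses, went from 4.95 ± 1.53 to 8.35 ± 0.103 CPM, Ifit3 from 18.1 ± 4.11 to 28.5 ± 4.95 CPM and Oasl2 from 6.13 ± 2.43 to 11.6 ± 1.82 CPM (SD, n = 4). Unlike the microglial lists, Tg replicate 1 was not low here, at 0.69 against 0.55 to 0.64 in the other Tg libraries. NTg replicate 1 lay apart from its group, at 0.62 where the other NTg libraries lay between -0.25 and -0.13, and without it the list's median was 0.77. With it, only 2 of the 4 Tg libraries lay above all NTg libraries (exact two-sided permutation p = 0.0857). Of the 35 splits of the libraries into 4 and 4, 4, the real one included, gave this list as small a camera p. Camera gave adjusted p = 9.34e-18, and 0.196 with an estimated correlation. Of 18 cytokine and chemokine genes, 7 rose and 1 fell when adjusted over the list alone (median 0.60, camera adjusted p = 1.13e-07, 0.0850 with an estimated correlation). Some members, Cxcl10 and Ccl4 among them, are also in other lists, and without the shared members camera's adjusted p was 0.00488. Ccl4 went from 0.538 to 1.44 CPM and Tgfb1 from 3.91 to 5.95 CPM, while the member that fell was Tgfb2, from 16.3 ± 1.42 to 13.3 ± 1.33 CPM. Without Tg replicate 1, 7 cytokine genes rose over all genes. Antigen presentation genes had a median of 0.21 with 1 of 17, Ctss, rising when adjusted over the list alone (camera adjusted p = 0.00371, 0.593 with an estimated correlation). B2m, the light chain of class I molecules, was at 118 ± 41.9 CPM in NTg and 182 ± 18.3 CPM in Tg. That list's call was lost without NTg replicate 3 (median 0.12, adjusted p = 0.109), NTg replicate 4 (median 0.06, adjusted p = 0.0509) or Tg replicate 2 (median 0.20, adjusted p = 0.0676), and without the members it shares with other lists (adjusted p = 0.0949), and its median was 0.37 without NTg replicate 1.

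**Figure D1:**
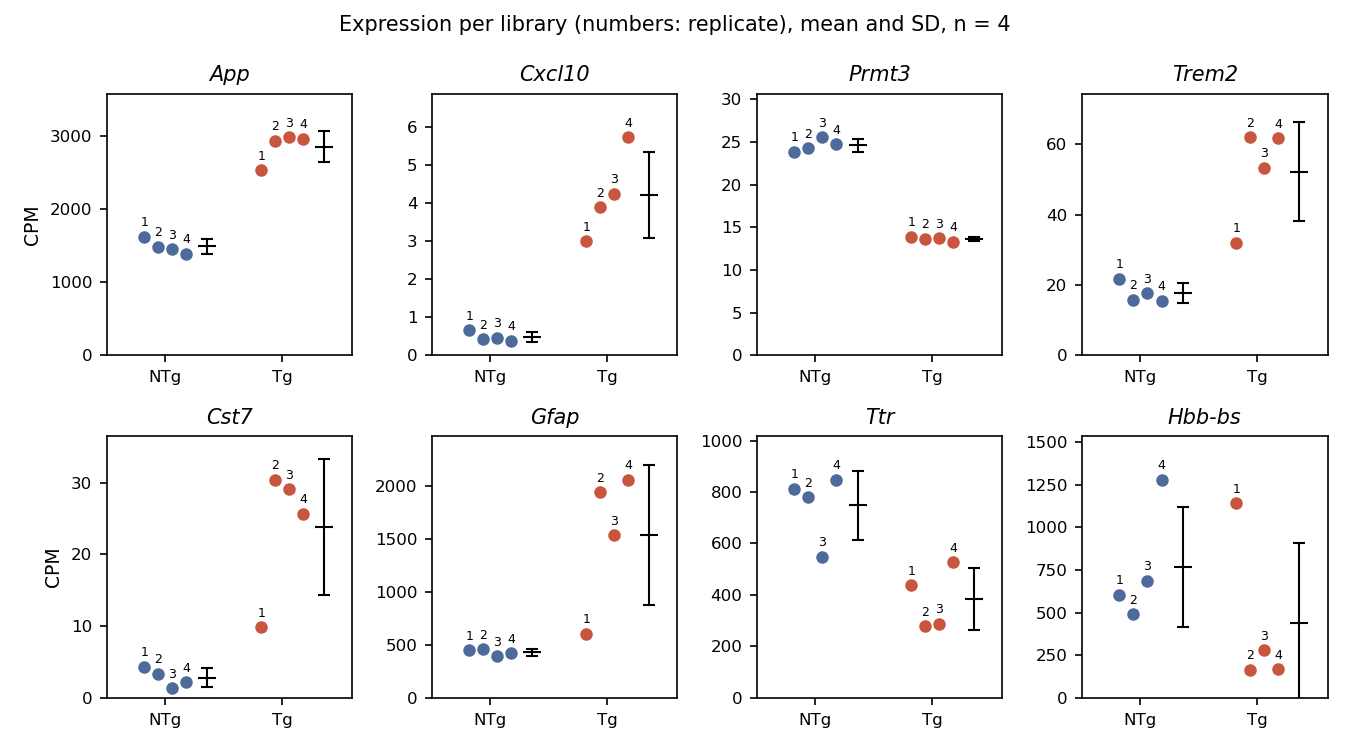
CPM of 8 genes in each library (points, numbered by replicate), with the mean and SD of each genotype (bars, n = 4). Prmt3 separates the genotypes with 13.3 to 13.9 CPM in Tg, while Trem2, Cst7 and Gfap are lower in Tg replicate 1 than in the other Tg libraries and Hbb-bs is higher in it.

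Reactive astrocyte genes stood higher in Tg, while general astrocyte markers went both ways. Of 20 reactive genes, 12 rose when adjusted over the list alone, with a median log2 fold change of 0.74. Gfap, the intermediate filament of reactive astrocytes, went from 431 ± 31.6 to 1534 ± 658 CPM (SD, n = 4; log2 fold change 1.83, SE 0.31; adjusted p = 0.00152 over the list alone and 0.107 over all genes). Serpina3n, a protease inhibitor, went from 43.1 to 143 CPM, Osmr, the oncostatin M receptor, from 6.79 to 20.6 CPM and Vim from 64.5 to 138 CPM. In the astrocyte identity list 10 members were higher and 5 lower (median 0.07), and when adjusted over the list alone 1 of 15 rose, the water channel Aqp4 (241 to 338 CPM), and 1 fell, Fgfr3 (108 to 90.7 CPM). The glutamate transporter Slc1a2, its most abundant member, was at 1961 ± 175 CPM in NTg and 1772 ± 155 CPM in Tg. The excess of the reactive over the identity list was 0.63 ± 0.31 in Tg and 0 ± 0.12 in NTg on the log2 scale (exact two-sided permutation p = 0.0286, n = 4, the smallest that 4 against 4 libraries can give). Camera gave adjusted p = 1.04e-11 for the reactive list, 0.182 with an estimated correlation, and 0.151 for the identity list, where fry's mixed test, which lets members move either way, gave an adjusted p of 0.00392. Gfap was 607 CPM in Tg replicate 1 and 1534 to 2057 CPM in the other Tg libraries, and without that replicate 11 reactive genes passed edgeR over all genes.

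All 22 genes tested for cholesterol synthesis and its regulation were higher in Tg by small amounts, and 17 rose when adjusted over the list alone (median log2 fold change 0.29). The enzyme Msmo1 went from 77.4 ± 2.54 to 94.0 ± 3.40 CPM, Fdft1 from 78.9 ± 3.53 to 101 ± 8.62 CPM, Sqle from 61.2 ± 1.74 to 76.1 ± 6.09 CPM and Hmgcs1 from 207 ± 15.7 to 255 ± 23.4 CPM (SD, n = 4). The mean of the list lay 0.20 to 0.39 above the NTg mean in the Tg libraries, and between -0.01 and 0.01 of it in the NTg libraries. Camera gave adjusted p = 2.16e-22, 0.0850 with an estimated correlation, and fry, which asks whether the members move one way on balance, gave an adjusted p of 0.0181. The test of edgeR called 0 of the 22 over all genes, or 6 without Tg replicate 1, and DESeq2 9.

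Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid, stood lower in Tg: 11 of 13 fell when adjusted over the list alone, with a median log2 fold change of -0.82. Ttr, the thyroid hormone carrier transthyretin, went from 748 ± 135 to 384 ± 121 CPM, Kl, which encodes klotho, from 26.2 ± 2.45 to 13.8 ± 2.97 CPM and Enpp2 from 637 ± 58.2 to 462 ± 55.5 CPM (SD, n = 4). Tg replicate 1, at -0.68, lay among the other Tg libraries at -1.01 to -0.45. Ependymal markers, from the lining of the ventricles, had a median of 0.0039, and 0 of 9 were called by edgeR or DESeq2. Camera gave adjusted p = 2.64e-18 for the choroid plexus list, 0.0850 with an estimated correlation, fry an adjusted p of 0.0181, and DESeq2 called 9 members over all genes where edgeR called 0, or 2 without Tg replicate 1. All 13 endothelial markers were lower (median -0.29, camera adjusted p = 1.49e-08, 0.196 with an estimated correlation), and 2 fell when adjusted over the list alone, the efflux pump Abcb1a (36.7 ± 2.15 to 29.8 ± 2.51 CPM) and the VEGF receptor Flt1 (61.1 ± 4.51 to 47.6 ± 7.59 CPM).

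Red blood cell transcripts varied between libraries of both genotypes. Haemoglobin genes summed to 1279 to 3253 CPM in NTg, 2988 CPM in Tg replicate 1 and 447 to 729 CPM in the other Tg libraries. The list was lower in Tg (median -0.84, camera adjusted p = 0.000105, 0.456 with an estimated correlation), with a median of -1.91 without Tg replicate 1 and -0.44 without NTg replicate 4. Hbb-bs, the most abundant member, was at 766 ± 351 CPM in NTg and 438 ± 471 CPM in Tg (SD, n = 4), and 0 of 7 members were called when adjusted over the list alone. Without Tg replicate 1, 4 of the 7 fell over all genes, Hbb-bs among them. Camera's call of the list was lost with the choroid plexus level as a covariate. It was also lost with the list's own level as a covariate. That loss was set in advance, since this covariate is the mean of the list's members.

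**Figure D2:**
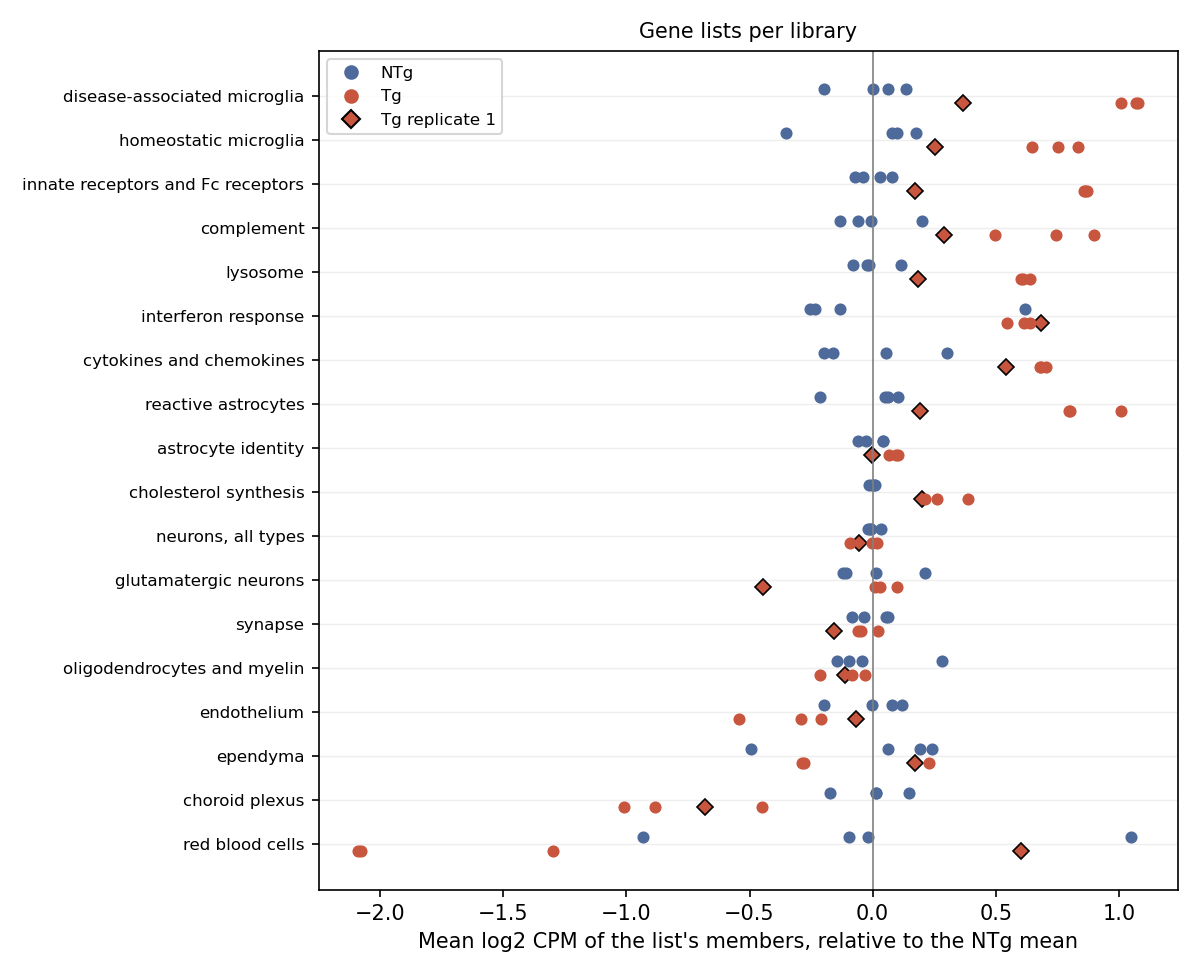
Mean log2 CPM of the members of 18 gene lists in each library, relative to the mean of the 4 NTg libraries. Each point is a library and the outlined diamond is Tg replicate 1, which lies at 0.37 in the disease-associated microglia list, where the other Tg libraries lie at 1.01 to 1.08.

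Neuronal and oligodendrocyte genes differed by small amounts, and 0 members of the lists in this paragraph passed edgeR over all genes or adjusted over the list alone, or DESeq2. General neuronal markers had a median log2 fold change of -0.04, glutamatergic markers -0.04 and GABAergic markers -0.01, and Snap25 was at 2490 ± 104 CPM in NTg and 2373 ± 152 CPM in Tg (SD, n = 4). Slc17a7, the vesicular glutamate transporter of cortex, was at 623 and 625 CPM, with 473 CPM in Tg replicate 1. Without that library the glutamatergic median was 0.07 and the GABAergic -0.12, neither called. Camera called glutamatergic markers lower without Tg replicate 2 (-0.13, adjusted p = 0.0339) and with the red blood cell covariate (-0.22, 2.26e-05), and general neuronal markers lower without Tg replicate 4 (-0.06, 0.0212). Camera placed 4 further lists lower and 1 higher, all with an adjusted p of 0.535 or more with an estimated correlation. They were synapse genes (median -0.05, adjusted p = 0.00423), immediate early genes (-0.13, 0.0144), oligodendrocyte and myelin genes (-0.15, 0.000414), nuclear genes of oxidative phosphorylation (-0.04, 0.00177) and, higher in Tg, cell division genes (0.13, 0.00579). Mitochondrially encoded genes were also lower (-0.08, 0.0261, and 0.706 with an estimated correlation). Many of the 35 splits of the libraries into 4 and 4 gave these lists as small a camera p. The number, the real split included, was 11 for synapse, 17 for immediate early, 13 for myelin and 10 for oxidative phosphorylation genes. It was 6 for cell division and 19 for mitochondrial genes. Mbp went from 3976 ± 310 to 3509 ± 407 CPM, Egr1 from 122 ± 30.9 to 106 ± 31.7 CPM and mt-Co1 from 21414 ± 2447 to 20282 ± 1136 CPM, none of them called. Each of these calls was lost without some single library. Without NTg replicate 1 the median was -0.04 for synapse (adjusted p = 0.0773), -0.06 for immediate early (0.130) and -0.06 for myelin genes (0.299). Without NTg replicate 3 it was -0.03 for synapse (0.109), -0.04 for immediate early (0.204) and -0.04 for mitochondrial genes (0.109). Without Tg replicate 1 it was -0.03 for synapse (0.232) and turned to 0.0041 for immediate early genes (0.917). Oxidative phosphorylation lost its call without Tg replicate 2 (median -0.02, adjusted p = 0.102). Cell division lost it without NTg replicate 2 with a median about as large (0.11, 0.0910). Mitochondrial genes lost it without NTg replicate 4 (-0.0026, 0.967) and, with a median moved by less than 1.5 times, without Tg replicate 2 (-0.07, 0.0540) or Tg replicate 4 (-0.06, 0.179). Beyond left-out libraries, mitochondrial genes lost the call with 1 surrogate variable, quality weights, and the red blood cell or choroid plexus covariate. Immediate early genes lost it with quality weights, and myelin and oxidative phosphorylation genes with the choroid plexus covariate. Other medians moved by over 1.5 times with the call kept, to -0.20 and -0.23 for immediate early genes without NTg or Tg replicate 2, to -0.07 for oxidative phosphorylation and -0.15 for mitochondrial genes without NTg replicate 1, and to -0.07 for synapse and 0.24 for cell division genes without NTg replicate 4.

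In the amyloid precursor processing list, which holds secretases, adaptors and clearance factors but not App, the median was -0.01 and 1 of 21 rose when adjusted over the list alone, the chaperone Clu (622 ± 31.0 to 839 ± 117 CPM, SD, n = 4). Camera did not call the markers of border-associated macrophages (median 0.22, adjusted p = 0.121), lymphocytes (-0.23, 0.803), neutrophils (-0.34, 0.0619), oligodendrocyte precursors (0.07, 0.405), pericytes and smooth muscle (-0.05, 0.346) or meningeal fibroblasts (-0.04, 0.620). The border-associated macrophage list was called higher without Tg replicate 1, in which it was low (median 0.42, adjusted p = 0.000363), and without NTg replicate 2 (0.33, 0.0292), and neutrophil markers were called lower under 9 of 18 alternatives. Nor did it call the regional markers of striatum (-0.09, 0.233), dentate gyrus (-0.005, 0.709), thalamus and midbrain (-0.28, 0.0619), hypothalamus (-0.26, 0.164), cerebellum and hindbrain (0.16, 0.414) or olfactory bulb (-0.02, 0.771). Of these, thalamus and midbrain was called lower under 10 of 19 alternatives and hypothalamus under 6 of 18, and without Tg replicate 1 both were (adjusted p = 0.0225 and 0.0455), as was striatum (0.0225, median -0.18). The unfolded protein response (-0.09, 0.104), heat shock (-0.01, 0.671) and circadian clock (-0.01, 0.376) lists were not called either. Fewer calls were gained by the unfolded protein response, lower under 4 of 19 alternatives, striatum, lower under 3, cerebellum and hindbrain, higher under 3, pericytes, meningeal fibroblasts and heat shock, each lower under 2, and olfactory bulb, lower under 1 of 18. Without NTg replicate 1 the meningeal median was -0.21 (adjusted p = 0.00824), and without NTg replicate 4 the cerebellar one was 0.33 (0.00607). Cerebellar markers were abundant in both genotypes, with Cbln3 at 183 ± 82.9 CPM in NTg and 245 ± 49.1 CPM in Tg. Gabra6 was at 104 ± 51.9 CPM in NTg and 141 ± 24.5 CPM in Tg. The tissue labelled forebrain may therefore hold some cerebellum, in amounts that may vary between libraries. Pituitary markers had 2 tested members, too few for the test.

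Of 41 lists tested, camera called 20, with 12 higher and 8 lower in Tg. With an estimated correlation between members it called 0, with a smallest adjusted p of 0.0850, and fry called 3, cytokines, choroid plexus and cholesterol synthesis. Fry's mixed test called 13, of which camera had called all but astrocyte identity. Over all genes, the first principal component held 21.9% of the variance and the second 19.1%, and the genotypes did not separate on either by an exact two-sided permutation test (p = 0.143 and 0.257). Tg replicate 1 lay at -19.6 on the first component, within the NTg range of -36.2 to 7, and the other Tg libraries lay at 16 to 26.8.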

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

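The tests in this part that set explanations for Tg replicate 1 against each other were chosen after its values were seen. In 224 sets of 4 libraries, a single library lay far from the other 3 of its genotype in 21, where chance gives about 11.2, and in 12 of these it was Tg replicate 1. Many of the sets share genes, so they are not independent.

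Tg replicate 1 was low in genes and lists of myeloid cells and of reactive astrocytes, the latter at 0.19 where the other Tg libraries lay at 0.80 to 1.01. It lay at 0.37 in the disease-associated microglia list (others 1.01 to 1.08), 0.17 in the innate and Fc receptor list (0.86 to 0.87), 0.20 in the Alzheimer risk list (0.62 to 0.67), 0.18 in the lysosome list (0.60 to 0.64), 0.54 in the cytokine list (0.68 to 0.71) and -0.34 in the border-associated macrophage list (0.47 to 0.52), all relative to the NTg mean on the log2 scale. Ctss was at 137 CPM (199 to 212) and the urea transporter Slc14a1, a gene chosen after its values were seen, at 29.5 CPM (38.2 to 39.9). The glutamatergic list lay at -0.45 (0.01 to 0.10) and App at 2532 CPM (2934 to 2980), while Hbb-bs, at 1141 CPM (165 to 280), and the haemoglobin sum, at 2988 CPM (447 to 729), were high.

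A mislabelled non-transgenic library is argued against, since App at 2532 CPM lay far above the NTg range of 1390 to 1623 CPM. Less cortex and hippocampus in the sampled tissue is not settled. The glutamatergic level was 0.711 of that of the other Tg libraries, while the excess in disease-associated microglia genes was 0.269 of theirs and that in Gfap 0.124. This ratio cannot bound the share of cortex, since the list also holds Slc17a6, a member of the thalamus and midbrain list. Among Tg libraries, replicate 1 lay highest in the striatum list (0.19, others -0.45 to 0.02). The same held for the thalamus and midbrain (0.07, others -0.37 to -0.10) and cerebellum and hindbrain lists (0.38, others -0.79 to 0.35). In the hypothalamus and olfactory bulb lists it lay within the range of the others. A lower transgene level may contribute but is not settled, as the App excess over NTg was 0.711 of that of the other Tg libraries, below each of them yet well above these 2 glial shares. That App share is about equal to the glutamatergic ratio. A lower transgene level therefore cannot be told apart from a lower glutamatergic content of this library. Lower amyloid load in this tissue is a biological explanation that these counts cannot test.

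NTg replicate 1 was high in Prnp (734 CPM, others 685 to 691), B2m (180 CPM, others 91.6 to 107), the Alzheimer risk list (0.26, others -0.10 to -0.07) and the interferon list (0.62, others -0.25 to -0.13), and low in nuclear oxidative phosphorylation genes (-0.063, others 0.02 to 0.03). NTg replicate 4 was high in Msmo1 (81.2 CPM, others 75.7 to 76.5) and NTg replicate 3 low in the reactive astrocyte list (-0.21, others 0.05 to 0.10). Tg replicate 2 was high in the dentate gyrus list (0.34, others -0.15 to -0.07), and Tg replicate 3 was high in the unfolded protein response list (0.15, others -0.10 to -0.09).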

How the results depend on the processing

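The alternatives with quality weights, the likelihood ratio test and the 2 cell-type covariates were chosen after seeing the data. Under each alternative test, scaling, filter, covariate or left-out library, App, Cxcl10 and Prmt3 were all called, except in 2. With the replicate block 1 gene, Prmt3, was called and App stood at 0.94 (adjusted p = 0.0838), and with the choroid plexus covariate, which nearly follows genotype, 0 genes were called (App 0.86, adjusted p = 0.504; 1381 genes at an unadjusted p under 0.05). Over all alternatives the adjusted p of App ran from 2.72e-33 to 0.504, and with single libraries left out its log2 fold change ran from 0.91 to 0.99. The permutation p of the first principal component stayed between 0.0571 and 0.514. The number of genes called was 3 with the planned test, 352 with DESeq2, 288 with the likelihood ratio test, 127 with no filter, 12 with quality weights and 5 with 1 surrogate variable. Leaving out single libraries it ranged from 3 to 314, the highest without Tg replicate 1, where 234 of the calls were shared with DESeq2. The cause of these differences was not tested. The block also leaves fewer residual degrees of freedom, whose share in the lost calls was not tested either. The number of lists called, 20, was 16 to 24 with single libraries left out, 0 with an estimated correlation, 3 with fry and 13 with its mixed test. Of the 20 lists, 9 were called under all 19 alternatives that kept the full lists and camera's preset correlation. Under all of these but the choroid plexus covariate, 3 more were called: homeostatic microglia, complement and choroid plexus. For the choroid plexus list that loss was set in advance, since the covariate is the mean of its own members. With an estimated correlation none of these lists was called. Called lists whose direction turned under an alternative, by the median or by camera, were mitochondrial genes (-0.15 to -0.0026 with single libraries left out, 0.0196 with the red blood cell covariate), immediate early genes (-0.23 to 0.0041 with single libraries left out), and, with the choroid plexus covariate, oxidative phosphorylation (0.0136), red blood cells (0.635, by the median alone) and the choroid plexus list itself (0.12). Lists without a call gained 47 over the alternatives, most often thalamus and midbrain, neutrophils and hypothalamus. For the remaining named genes, leaving out Sorl1, Ptk2b, Psap, Mertk, Cbln3 and Gabra6, 184 alternative values gained a call and 18 uncalled ones changed sign. The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at 0.07, -0.03, 0.16 and -0.01, and of the Tg libraries only replicate 3 matched its own number best. The Y-linked covariate was not run since the libraries do not differ in these genes, and robust dispersion and plain limma-voom give no list count of their own. At these depths counting error is small for abundant genes, and the spread between libraries sets the precision.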

Other observations

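Outside the gene lists, genes that DESeq2 called but edgeR did not included several of known myeloid and glial roles, all chosen after their values were seen. Cd180, a Toll-like receptor homologue, was at 2.65 ± 0.346 CPM in NTg and 5.92 ± 0.937 CPM in Tg (SD, n = 4; DESeq2 adjusted p = 6.00e-10, edgeR 0.0641), and Lyn, a Src-family kinase, at 12.6 ± 0.603 and 18.8 ± 1.66 CPM (8.89e-08, edgeR 0.0723). Cyba, a subunit of the NADPH oxidase, was at 5.44 and 10.3 CPM (DESeq2 adjusted p = 9.54e-05). The cytokine Lif was at 0.673 and 1.73 CPM (8.11e-05), and Stat3, a transcription factor downstream of its receptor, at 63.0 and 81.8 CPM (0.00122).

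Among the lower genes, Slc2a12, a sugar transporter, was at 7.02 ± 0.361 CPM in NTg and 4.75 ± 0.224 CPM in Tg (DESeq2 adjusted p = 1.66e-06, edgeR 0.0973), and Kirrel2, an adhesion molecule, at 3.17 and 1.78 CPM (7.93e-05). Slco1c1, which carries thyroid hormone across the blood-brain barrier, was at 52.0 and 39.7 CPM (0.000389), and the glutamate receptor gene Grm3 at 50.6 and 39.4 CPM (0.00103). In each of these 4 genes all Tg libraries, replicate 1 included, lay below all NTg libraries.

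Over all tested genes, 566 had all Tg libraries above all NTg libraries and 341 had them all below, together 4.20% where chance gives 2.86%. The tests on the choroid plexus were chosen after its values were seen. The test on Prmt3 was chosen after Prmt3 stood out but before its neighbours were counted, and the tests on other groupings before these were fitted.

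Of the 35 splits of the 8 libraries into 4 and 4, 2, the real one included, called at least its 3 genes, and the highest other split called 4, so chance is not excluded for the number of genes. That split exchanged Tg replicate 1 with NTg replicate 1. For lists, 9 splits reached the 20 of the real one and the highest other gave 24, so the number of lists does not exclude chance either; the median over the other splits was 16.5. The real split gave the smallest camera p of all 35 for 9 of the 41 lists, namely both microglia lists, innate receptors, complement, lysosome, cytokines, reactive astrocytes, choroid plexus and cholesterol synthesis.

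Prmt3 was lower by nearly the same amount in every Tg library, at 13.3 to 13.9 CPM against 23.8 to 25.6 CPM. A candidate explanation is a locus linked to the transgene, such as an insertion site or a chromosome segment of another strain. Of the 20 tested genes nearest to Prmt3, 3 had an edgeR p under 0.05, against a median of 1 and a 95th percentile of 4 over 20667 other windows, so the test does not decide. These 3, Slc6a5, Nell1 and Slc17a6, lay on the same side of Prmt3 and were all lower in Tg, with adjusted p = 0.253 over the 20 neighbours, and Slc17a6 belongs to the thalamus and midbrain list, whose 8 members were all lower. A strain variant that keeps reads from aligning, and an effect of APP itself, were not tested.

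The choroid plexus markers could be lower because less ventricular wall was sampled, but the ependymal median of 0.0039 (bootstrap SE 0.10) lay far above the choroid plexus median of -0.82. That SE resamples the ependymal genes, not the libraries, so it leaves out the spread between libraries. Ependymal values per library lay at -0.50 to 0.24 in NTg and -0.29 to 0.23 in Tg. Those of the choroid plexus lay at -0.175 to 0.146 and -1.01 to -0.45, without overlap. This argues against less ventricular wall as the whole cause. A smaller share of choroid plexus cells would lower its markers alike, and the 13 members scattered around a common log2 change of -0.69 about as much as their errors allow (chi-square test of heterogeneity with errors from edgeR, p = 0.0558). Without Enpp2, which oligodendrocytes also express, that p was 0.36, but members that vary together across libraries make such scatter look small. Whether a smaller share came from dissection or from the tissue of Tg mice cannot be told from these counts.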
